A study of Mus musculus with 3 samples.

How the data were processed

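A single comparison was analysed: mouse liver total RNA against Universal Mouse Reference RNA (UMRR) on 3 arrays of 2 colours. Per the labels, both RNAs were purchased, cRNA was made from each by a single round of amplification, UMRR was labelled with Cy3 and liver with Cy5. The labels do not say whether each array had its own amplification. All arrays have the same dye orientation, so dye bias does not cancel.

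The deposited table holds 1 signed value per probe and array, read here as a log2 ratio of both dyes as processed by the authors. The scanner, background correction, dye normalization, filters and log base are not given in the sources used here. Base 2 was assumed from the values, which lie on both sides of 0 and reach wider than log10 ratios of a scanner would be; natural logs were not excluded, and would multiply every log2 value by 1.44. The deposited median, with exact zeros included, was 0 on each array. Exact zeros made up 32.2%, 23.5% and 29.6% of the values of arrays 1, 2 and 3, while 121, 153 and 140 other values lay within 0.01 of 0. They were therefore read as placeholders for no measured ratio. Of the probes at exact 0 on array 1 alone (995), array 2 alone (293) and array 3 alone (558), the mean of the other arrays was at least 2-fold from a ratio of 1 in 19.5%, 17.4% and 27.8%. What the authors' procedure did to give these zeros is not given in the sources used here. Leaving them out removes genes that were measured on only some arrays. Scanner intensities were not used here, so no filter on dim probes could be applied.

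Probes were named from the platform annotation: 12336 had 1 symbol, 61 several and 3876 none. Of the 12336, 12228 matched the reference gene table (assembly GRCm38.p6, used for names only) by gene identifier and 108 did not and kept the annotation's symbol; 0 symbols changed. The genome build behind the array is not given in the sources used here, and no coordinates are printed. Probes with several symbols or none entered only the fit on single probes.

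The direction of the ratios was set by a list of hepatocyte secretory genes, of which 4 were measured. Probes with a measured ratio on all 3 arrays (9910) entered. Probes of 1 symbol were averaged per array, which gave 5520 genes, and 1328 of them had at least 2 probes. The median difference between the highest and lowest probe of a gene was 0.34, and 12 genes had probes at least 1 log2 unit from 0 on both sides. An intercept was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 and tested two-sided against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit was run on probes. Because the arrays repeat 1 pair of RNAs, the count of genes at least 2-fold apart on every array was also made, with no test. The 25 gene lists were compared with camera, two-sided, with a preset correlation of 0.01, where at least 3 members were measured (17 lists). Members were counted over all genes and adjusted over the list alone.

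Genes named in the text were chosen by a rule. It took the 6 highest and the 6 lowest genes by mean log2 ratio among those past the test with 1 sign on all arrays. Of each list it took the 2 members past the test with the largest absolute mean, or the 2 largest absolute means where fewer passed, and the member past the test that went furthest against the median of its list. Outside the rule, the text names the other measured members of the hepatocyte list, and genes of pancreatic acinar cells, which were chosen after their values were seen. The other measured erythroid genes and Fabp1 are also named outside the rule, after their values were seen. The rule, the lists, the tests and most alternatives were set before the data were examined. A further 9 lists, for acinar cells, islets and other organs, were written afterwards.

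The gene fit was tested on simulated data with 5520 genes, 200 of them changed, in 20 simulations. It recovered 31.8% of changes of 0.5 on the log2 scale, 72.6% of changes of 1 and 93.9% of changes of 2. Of the calls, 3.18% were false. In the data 3535 of 5520 genes passed, far more than 200, so the adjusted threshold was less strict there. The shares recovered and falsely called therefore do not carry over to the real fit. In simulated lists of 10 genes, camera called 2.5% of unchanged lists and 100% of lists shifted by 2, at an unadjusted p under 0.05. The simulated noise was independent between genes, while the estimated correlation in the real lists reached 0.88. The simulation therefore does not give the share of false calls for lists of correlated genes.

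The alternatives were centring or scaling of the arrays, leaving out each array, letting in probes with values on at least 2 arrays, the median probe per gene, eBayes with trend and robust set, a test without moderation of the variance, and removal of probes with an SD above the 95th percentile. Further alternatives were a test against a 2-fold difference, a threshold of 0.01, camera with an estimated correlation or on ranks, and correlations of arrays on probes or on genes at least 2-fold apart. Exact zeros kept as ratios of 1, natural logs, medians of blocks of 500 probe numbers subtracted, and gene lists without array 1 were added after seeing the data.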

Results

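Gene expression in mouse liver was compared with that in Universal Mouse Reference RNA (UMRR), a commercial pool of RNA from mouse cell lines that serves as a common reference on arrays. Purchased liver total RNA was labelled with Cy5 and UMRR with Cy3 on each of 3 arrays, with no dye swap. The arrays formed 1 group of 3 replicates. The labels name 1 catalogue product for each RNA, so the arrays are repeats of 1 RNA pair. Every p-value of a single gene or probe below therefore measures the spread between arrays, which may be technical, and not the spread between livers. The camera p-values compare the genes of a list with all other genes, and do not measure the spread between livers either. Each array carried 16273 probes, of which 12336 had 1 gene symbol, 61 had several and 3876 were unnamed here. An exact 0 was listed for 5238 probes (32.2%) on array 1, 3832 (23.5%) on array 2 and 4823 (29.6%) on array 3, and was read as no measured ratio. A ratio on all 3 arrays was found for 9910 probes, which gave 5520 genes. The number of arrays limits the precision.

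The deposited log ratios do not state their base or direction. Base 2 was assumed; if they are natural logs, every log2 value below is too small by a factor of 1.44. The direction was taken from a list of hepatocyte secretory genes fixed before the data were examined. Its 4 measured members, Apoc3, Ambp, Rbp4 and Vtn, were above 0 on each array, with a median of 4.57 and a range of 4.01 to 5.17. Positive values were therefore read as higher in liver, and these 4 genes are no finding. The median of each array was 0 as deposited, with exact zeros included. Over the probes measured on all 3 arrays it was -0.019, -0.018 and 0.0045 on arrays 1, 2 and 3. Dye bias is part of every ratio.

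The ratios repeated closely across genes. Pearson's r was 0.93 between arrays 1 and 2, 0.94 between arrays 1 and 3 and 0.98 between arrays 2 and 3, with Spearman's rho of 0.87, 0.89 and 0.96. These are correlations across genes, which are not independent replicates. The SD of the difference between arrays 2 and 3 was 0.21, against 0.43 for arrays 1 and 2 and 0.38 for arrays 1 and 3. Array 1 thus stood farther from the other arrays than these stood from each other. The sign was shared by 83.5% of genes on arrays 1 and 2, 84.7% on arrays 1 and 3 and 90.7% on arrays 2 and 3. No gene had identical values on any pair of arrays. The median SD of a gene between arrays was 0.17.

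**Figure D1:**
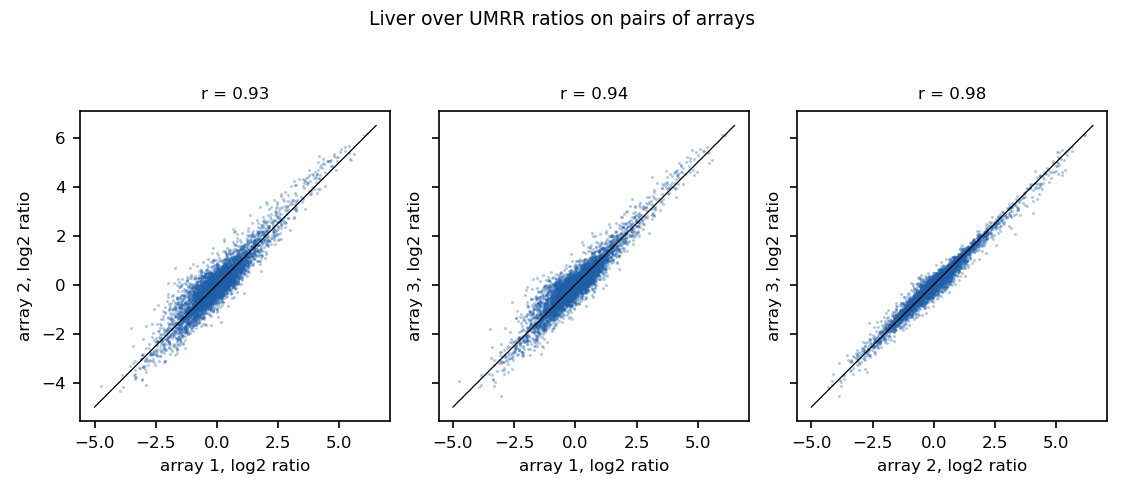
Log2 ratios of liver over UMRR for 5520 genes on each pair of the 3 arrays, 1 point per gene, with the line of equality. The points of arrays 2 and 3 lie closest to the line (r = 0.98), and those of array 1 spread more widely against array 2 (r = 0.93) and array 3 (r = 0.94).

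Among the tested gene lists, amino acid breakdown had the highest median log2 ratio (4.12, with 6 of 6 measured genes higher in liver) and cell cycle the lowest (-2.23, with 16 of 17 lower). Aadac, a deacetylase of the endoplasmic reticulum (probe 2477), had the highest ratio, at a log2 value of 6.14 ± 0.042 (SD, n = 3 arrays) or 70.6-fold. Baat, which conjugates bile acids to amino acids (probe 15962), followed at 6.08 ± 0.083 or 67.6-fold. At the other end stood 2410003L11Rik (probe 953), at -4.27 ± 0.43 or 19.3-fold lower in liver. Cdk1, the kinase that drives entry into mitosis (probe 6415), was 17.7-fold lower, at -4.15 ± 0.19. The lowest place of 2410003L11Rik rested on array 1 (-4.76). On arrays 2 and 3 it stood at -4.14 and -3.92, above Cdk1 (-4.33 and -4.16).

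The other genes of the highest group were Reg2, Try4, C8g and Mtarc1. Reg2 (probe 11741) and Try4, a trypsin (probe 13309), are genes of the exocrine pancreas, and their log2 values were 5.55 ± 0.14 and 5.38 ± 0.26 (SD, n = 3). C8g, a subunit of complement component C8 (probe 13072), stood at 5.44 ± 0.20, and Mtarc1, a mitochondrial reductase (probe 10496), at 5.38 ± 0.0063. Among the lowest were Pbk, a mitotic kinase (probe 9151), at -4.03 ± 0.17 and Steap1, a membrane protein (probe 2513), at -3.83 ± 0.75. Lockd, a long noncoding RNA (probe 1210), stood at -3.76 ± 0.41 and Myof, a membrane repair protein (probe 840), at -3.76 ± 0.10. The adjusted p-values of these 12 genes in the limma fit lay between 1.76e-06 for Aadac and 5.32e-05 for Steap1. Each of the 12 was measured by 1 probe, and a probe of the trypsin family can take up RNA of related genes, so the value of Try4 is uncertain.

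In the limma fit with Benjamini-Hochberg adjustment, 3535 of 5520 genes (64.0%) differed from a ratio of 1 at an adjusted p of 0.05. Of these, 1663 were higher in liver and 1872 lower. A mean difference of at least 2-fold was found for 1375 of them, 647 higher and 728 lower. The count without any test, of genes at least 2-fold apart with 1 sign on every array, was 1048 (522 higher and 526 lower). A ratio of at least 16-fold was reached by 54 genes on the liver side and by 3 on the UMRR side. On single probes, named or not, 6427 of 9910 passed, 3110 higher and 3317 lower. The smallest absolute mean log2 value that passed was 0.25. Without moderation of the variance 2087 genes passed, and 816 passed a test against a 2-fold difference. Read as natural logs, 1598 genes were at least 2-fold apart on every array. With exact zeros kept as ratios of 1, a setting chosen after seeing the data, 13 of the 59 called genes that the rule named lost their call with the direction kept, and Gstz1 lost it with the sign turned (0.55, adjusted p = 0.311). Of the 13, Pon3, Psmb5, Rps29, Krt5 and Psmc3 had the same log2 value as before. The log2 value was 4.43 for Try4, 2.93 for Gldc, 3.32 for Hba-a2, 1.31 for Cp, 1.43 for Cyc1, 0.54 for Cldn3, 0.66 for Cdkn1c and -0.98 for Rpl23.

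**Figure D2:**
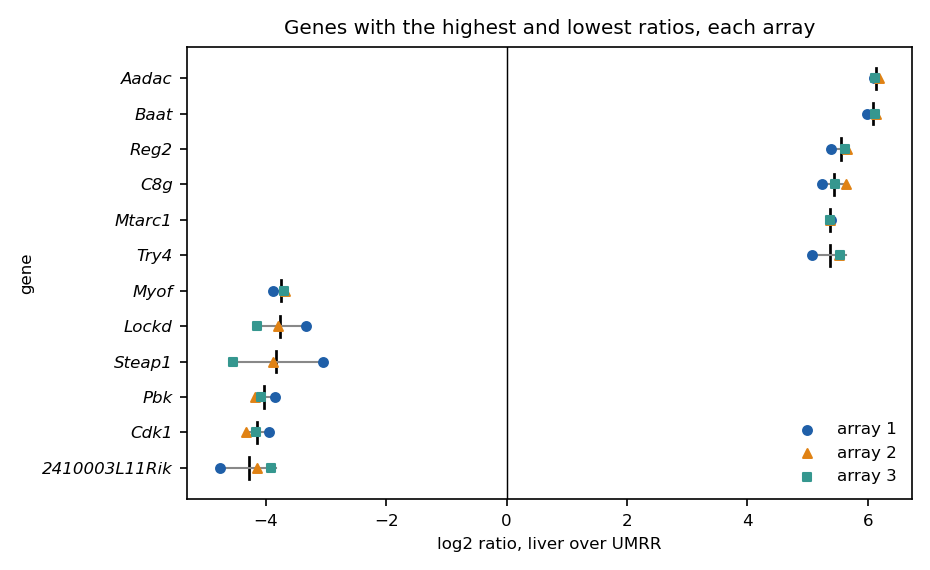
Log2 ratios of liver over UMRR on each of the 3 arrays for the 6 genes with the highest and the 6 with the lowest mean, with a vertical tick at the mean and a horizontal line of ± 1 SD. Aadac stands highest at 6.14 and 2410003L11Rik lowest at -4.27, and the arrays lie farthest apart for Steap1 (SD 0.75).

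Gene lists for the functions of liver had been fixed before the data were examined. Genes of amino acid breakdown and the urea cycle were higher in liver, with 6 of 6 measured members past the test and a median log2 value of 4.12. They included Gldc of the glycine cleavage system (5.33 ± 0.26, SD, n = 3) and Gnmt, a glycine methyltransferase (4.98 ± 0.27). All 6 measured genes of bile acid synthesis and transport were higher too, with a median of 3.15; besides Baat they included Nr1h4, the bile acid receptor FXR (3.84 ± 0.41). Of 10 detoxification genes, 8 were higher, 1 was lower and 1 did not pass, with a median of 2.33. Sult1d1, a sulfotransferase, stood at 5.38 ± 0.14 and Fmo5, a flavin monooxygenase, at 4.64 ± 0.55. Gstz1, an enzyme of tyrosine breakdown, went against the list at -0.33 ± 0.13. Its call was lost without array 2 (adjusted p = 0.146) and without array 3 (adjusted p = 0.207), and its sign turned when probes with values on at least 2 arrays were let in (0.77, adjusted p = 0.118).

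Genes of fatty acid oxidation and ketone synthesis were higher for 8 of 9 members, with a median of 1.53. Among them were Bdh1, which acts on ketone bodies (4.31 ± 0.13, SD, n = 3), and Decr1, which acts on unsaturated fatty acids (4.07 ± 0.14). The member that did not pass was Fabp1, on 1 probe, at -0.078 ± 0.074. The 3 measured liver transcription factors were all higher, with a median of 2.97, including Klf15 (3.97 ± 0.38) and Hhex (2.97 ± 0.18). Of 4 genes of cholesterol synthesis, 3 were higher, with a median of 1.20, among them Ebp (3.16 ± 0.084) and Fdft1 (1.79 ± 0.31).

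In the camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 17 lists, the adjusted p was 0.000281 for amino acid breakdown, 0.000285 for bile acids and 0.000235 for detoxification. It was 0.000317 for fatty acid oxidation and 0.00695 for the transcription factors. With an estimated correlation none of these passed. The adjusted p was then 0.236 for amino acid breakdown, detoxification and fatty acid oxidation, 0.316 for bile acids and 0.313 for the transcription factors. In that setting camera uses the few degrees of freedom left by 3 arrays, so a list could hardly pass. It therefore cannot decide whether these lists hold. The estimated correlation lay below the preset 0.01 for detoxification (-0.056) and fatty acid oxidation (-0.055), so a higher correlation was not what removed their calls. Cholesterol synthesis did not pass, with an adjusted p of 0.0608, and passed without array 1 at 0.0173. With exact zeros kept as ratios of 1, which lets in probes with exact zeros, 3 of 8 genes of amino acid breakdown passed with a median of 2.55, 5 of 12 genes of fatty acid oxidation passed, and so did 3 of 5 transcription factors with a median of 1.54 and 2 of 7 genes of cholesterol synthesis with a median of 0.35. Adjusted over the list alone, the counts of these 6 lists were the same as over all genes.

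Liver lists with fewer than 3 measured members were not tested as lists. F11, coagulation factor XI, stood at 5.33 ± 0.17 (SD, n = 3) and C1ra, a complement protease, at 2.11 ± 0.18. The acute phase genes Cp (1.84 ± 0.29) and Saa3 (1.20 ± 0.10) were higher in liver, as were Apoe, an apolipoprotein (4.16 ± 0.46), and Pon3, an esterase of lipoproteins (1.08 ± 0.47). Khk, the fructokinase, stood at 3.72 ± 0.44. Each of these 7 genes passed the limma test with the same sign on every array, though Pon3 did not without moderation of the variance (adjusted p = 0.102). Of 8 cytochrome P450 genes on the array, Cyp1b1 alone had a ratio on all 3 arrays, at 0.080 ± 0.15 with an adjusted p of 0.522. With exact zeros kept, 1 of 4 acute phase genes, 1 of 6 lipoprotein genes and 0 of 8 cytochrome P450 genes passed. Cyp1b1 passed after the median of each block of probe numbers was subtracted, another setting chosen after seeing the data (0.27, adjusted p = 0.0489), under which Rps29 (adjusted p = 0.0965) and Krt5 (adjusted p = 0.128) lost their calls. Adjusted over the list alone, the counts of these lists did not change.

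**Figure D3:**
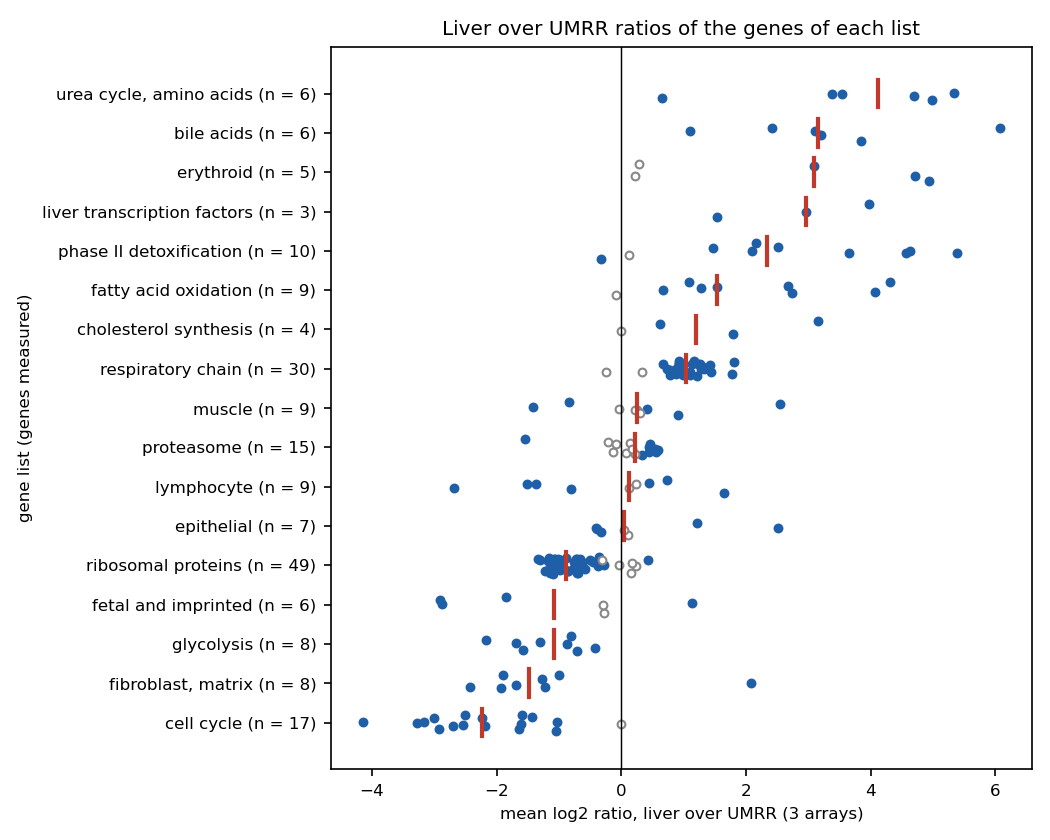
Mean log2 ratio of liver over UMRR for each measured gene of the 17 tested lists, with filled points for genes past the test, open points for the others and a red line at the median of the list. Amino acid breakdown has the highest median (4.12) and cell cycle the lowest (-2.23).

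Lists of housekeeping complexes and of growth were compared next. Genes of the respiratory chain and ATP synthase were higher in liver for 28 of 30 members, with a median log2 value of 1.04, including Sdhb of complex II (1.81 ± 0.27, SD, n = 3) and Cyc1 of complex III (1.78 ± 0.12). Genes of the cell cycle and DNA replication were lower for 16 of 17 members, with a median of -2.23. Stmn1, a regulator of microtubules, stood at -3.28 ± 0.25 beside Cdk1. Cytoplasmic ribosomal protein genes were lower for 43 of 49 members, with a median of -0.89, among them Rpl23 (-1.33 ± 0.28) and Rplp0 (-1.31 ± 0.14). The list for glycolysis and lactate was made of forms used by most growing cells, so it does not stand for the whole pathway. All 8 of its measured genes were lower, with a median of -1.08. They included Hk2, a hexokinase (-2.17 ± 0.51), and Pfkp, a phosphofructokinase (-1.70 ± 0.39).

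One ribosomal protein gene, Rps29, went against its list at 0.43 ± 0.18 (SD, n = 3), and its call was lost without array 3 (adjusted p = 0.0551). Without array 1, 2 genes of that list were higher. Many ribosomal protein genes have near-identical pseudogenes, so their single values are uncertain. Of 15 proteasome genes, 7 were higher, 1 was lower and 7 did not pass, with a median of 0.22; without array 1, 8 were higher and 4 lower. Psmb5 stood at 0.59 ± 0.19, and Psmc3 went the other way at -1.55 ± 0.51. Without moderation of the variance the adjusted p was 0.0701 for Psmb5, 0.0704 for Psmc3 and 0.0959 for Rps29.

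The camera test gave adjusted p-values of 5.78e-08 for the respiratory chain, 9.32e-08 for cell cycle, 7.39e-08 for ribosomal proteins and 0.00363 for glycolysis. With an estimated correlation the adjusted p was 0.236 for the respiratory chain, ribosomal proteins and glycolysis and 0.313 for cell cycle. None passed, but with the few degrees of freedom left by 3 arrays a list could hardly pass in that setting. The proteasome list did not pass, with an adjusted p of 0.140, and passed at 0.0431 when exact zeros were kept as ratios of 1, though with 2 of 16 single genes past the test. With zeros kept, 15 of 32 cell cycle genes were lower with a median of -0.96, and 5 of 10 glycolysis genes with a median of -0.64. Of 33 respiratory chain genes 20 were then higher, with a median of 0.81. Of 51 ribosomal protein genes 33 were lower and 1 higher, with a median of -0.72. Adjusted over the list alone, 2 ribosomal protein genes were higher and 44 lower, and 29 genes of the respiratory chain were higher and 1 lower. The counts of the cell cycle, glycolysis and proteasome lists were the same as over all genes.

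Lists for cell types that either RNA could hold were compared last. Fibroblast and matrix genes were lower in liver for 7 of 8 members, with a median log2 value of -1.48, including Anxa2, an annexin (-2.43 ± 0.29, SD, n = 3). Lum, a matrix proteoglycan, went against them at 2.08 ± 0.15. Erythroid genes were higher for 3 of 5 members, with a median of 3.09, and for 5 of 5 without array 1. The 3 were all globin genes. Hbb-bh1 stood at 3.09 ± 0.67. The alpha globin genes Hba-a1 (4.94 ± 0.34) and Hba-a2 (4.72 ± 0.35) are near-identical, so their probes cannot separate them. The other members, Slc4a1 (0.28 ± 0.18) and Epor (0.22 ± 0.11), did not pass with all 3 arrays. Slc40a1, the iron exporter and the measured gene of the Kupffer cell list, stood between 3.91 and 4.13 on the 3 arrays. Of the endothelial list, Eng stood at 1.63 ± 0.35 and passed, and Ramp2 stood at 0.16 ± 0.14 and did not (adjusted p = 0.198).

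Fetal and imprinted growth genes were lower for 3 of 6 members, higher for 1 and not past the test for 2, with a median of -1.07. Dlk1 stood at -2.91 ± 0.22 (SD, n = 3) and Grb10 at -2.88 ± 0.23, while Cdkn1c, a cell cycle inhibitor, stood at 1.14 ± 0.16. Lymphocyte genes went both ways, with 3 of 9 higher and 4 lower. Pou2af1, a B cell coactivator, stood at -2.69 ± 0.16 and Ighm, the heavy chain of IgM, at 1.65 ± 0.41. The median of that list was 0.13, and its mean (-0.35) and its test pointed the other way. Muscle genes were higher for 3 of 9 (5 without array 1) and lower for 2, with a median of 0.26, including Tnnt2 (2.54 ± 0.067) and Actc1 (-1.42 ± 0.21). Epithelial genes were higher for 2 of 7 and lower for 3, with Ocln at 2.51 ± 0.31, Cldn3 at 1.22 ± 0.21 and Krt5 at -0.41 ± 0.29. The call of Krt5 was lost without array 2 (adjusted p = 0.0626). The epithelial median was 0.039, and -0.042 without array 2 and -0.015 without array 3. Without moderation of the variance the adjusted p was 0.0514 for Ighm and 0.189 for Krt5.

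The camera test gave an adjusted p of 0.00695 for both the fibroblast and the erythroid list. With an estimated correlation the adjusted p was 0.236 and 0.399, so neither passed. With exact zeros kept, 6 of 15 fibroblast genes were lower and 1 higher with a median of -0.47, and 1 of 7 erythroid genes was higher with a median of 0.67. Of 10 fetal and imprinted genes 3 were then lower and 0 higher with a median of -0.31, the muscle and lymphocyte medians were 0.11 and 0.049, and 3 of 9 epithelial genes passed. The epithelial median was 0.22 after block medians were subtracted. The adjusted p was 0.0886 for fetal and imprinted genes, 0.328 for muscle and 0.713 for both lymphocyte and epithelial genes, none of which passed. Adjusted over the list alone, 4 erythroid genes and 4 muscle genes were higher, and the counts of the other lists of cell types did not change. In all, 11 of 17 tested lists passed, 7 higher and 4 lower, and 11 passed in the camera test on ranks. With an estimated correlation 0 passed, and the unadjusted p was under 0.05 for 1 list. That setting uses the few degrees of freedom left by 3 arrays, so a list could hardly pass. It cannot decide whether the lists hold.

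Genes of pancreatic acinar cells, a list written only after the ratios had been seen, were also higher in the liver channel. Of 24 measured members, 23 passed the test as higher, with a median log2 value of 3.40. That median includes 10 genes whose high ratios had been seen before the list was written; over the other 14 it was 2.23. The 24 genes included Ctrb1, a chymotrypsinogen (4.86 ± 0.29, SD, n = 3), Clps, the colipase (4.55 ± 0.24), and Cpa1, a carboxypeptidase (3.47 ± 0.23), besides Reg2 and Try4; of these 5, Cpa1 alone was among the 14. Cel, a lipase, stood at 0.22 ± 0.079 and did not pass (adjusted p = 0.0821). Amy2a5, the pancreatic amylase, stood at 0.53 ± 0.20.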

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

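Keeping exact zeros, natural logs, block medians and gene lists without array 1 were tests chosen after the results were seen. The count of 3535 genes, of 5520 tested, was 2755 to 4004 when 1 array was left out (without array 3 and without array 1). It was 2391 to 3777 under 8 other settings at the same threshold. The 2391 were of 7984 genes, with zeros kept, and the 3777 of 6329, with values on at least 2 arrays. The count fell to 2087 without moderation of the variance and was 2739 at an adjusted p of 0.01. None of the genes shared with the 3535 changed sign, except 1 under the median probe. Genes at least 2-fold apart numbered 1348 to 1392 with 1 array left out and 816 in a test against a 2-fold difference. Read as natural logs, 1598 genes were at least 2-fold apart on every array (1048 in base 2). With an estimated correlation 0 of 11 lists passed. In that setting camera uses the few degrees of freedom left by 3 arrays, so a list could hardly pass. The adjusted p was then 0.236 for detoxification, amino acid breakdown, fatty acid oxidation, glycolysis, ribosomal proteins, the respiratory chain and fibroblast genes. It was 0.316 for bile acids, 0.313 for liver transcription factors and cell cycle and 0.399 for erythroid genes. The estimated correlation was below the preset 0.01 for detoxification (-0.056), fatty acid oxidation (-0.055), glycolysis (-0.034), ribosomal proteins (-0.0070) and fibroblast genes (-0.12). A higher correlation was thus not what removed those calls, which leaves the fewer degrees of freedom. It was above 0.01 for the other lists that lost the call, up to 0.85 for bile acids and 0.88 for erythroid genes. For these lists the higher correlation and the fewer degrees of freedom cannot be told apart. The cholesterol list passed without array 1 (0.0173) and the proteasome list with zeros kept (0.0431). The medians of 20 of the 25 lists moved by more than the spread between arrays with zeros kept, and none of these 20 changed sign; for example the median of the cell cycle list was -0.96, of amino acid breakdown 2.55 and of erythroid genes 0.67. None of the 11 lists then lost its camera call. Among genes at least 2-fold apart, r was 0.976 for arrays 1 and 2 and 0.980 for arrays 1 and 3. Of 730 values of 61 named genes, 701 kept direction and side of the threshold, 26 lost the call, 1 gained it and 2 reversed and lost the call, both Gstz1, at 0.77 with values on at least 2 arrays and 0.55 with zeros kept. The epithelial median of 0.039 ranged from -0.042 to 0.056 with 1 array left out and reversed without array 2 and without array 3 (-0.015); it was 0.22 with block medians subtracted. Fewer arrays leave fewer degrees of freedom, and so does an estimated correlation in camera. The cause of the other changes was not tested. No paired analysis was possible because there is 1 group, with each ratio formed within an array. Signal over background was not analysed here, so what dim probes limit is unknown.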

Other observations

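Of the tests below, the one on turned signs was set before the results were seen; the tests on acinar genes and on array 1 were chosen after them.

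Beyond the acinar genes already given, the ratios held 1810009J06Rik, a gene of the trypsin family, at 5.25 ± 0.21 (SD, n = 3), Rnase1, the pancreatic ribonuclease, at 4.67 ± 0.18, and Gp2, a zymogen granule protein, at 4.50 ± 0.32. The lipase Pnliprp2 stood at 4.45 ± 0.30, the chymotrypsin-like protease Ctrl at 4.41 ± 0.29, the elastase Cela3b at 4.30 ± 0.37 and the carboxypeptidase Cpb1 at 3.87 ± 0.30. Genes of pancreatic islets differed less, with a median of 0.74 over 5 measured genes, 4 of them higher and 1 lower, and 0 of the 5 at least 2-fold apart. The medians of the lists of other organs were 0.33 for stomach (13 genes, 8 higher and 1 lower), 0.71 for intestine (5 genes, 4 higher and 1 lower) and 0.36 for brain (7 genes, 5 higher and 1 lower). They were 0.065 for placenta (8 genes, 2 higher), -0.056 for testis (16 genes, 4 higher and 2 lower) and 0.16 for tongue and skin (7 genes, 3 higher and 2 lower). At least 2-fold higher were 7 of all 56 genes of these organs, among them 3 of stomach and 2 of intestine.

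A hypothesis for the acinar genes is that the liver RNA, which was purchased as total RNA with no sort or gate, may have held some RNA of pancreas. Cross-hybridisation among trypsins as the whole cause is argued against by acinar genes outside the serine proteases: their median was 2.48 over 17 genes and 1.64 over the 11 not looked at before (1.32, 2.00 and 1.71 on arrays 1, 2 and 3). The 56 genes of 6 other organs were not raised as far as a set. Their median was 0.27 (0.25 over the 50 not looked at before), against 2.23 for the 14 acinar genes not looked at before. The 56 were picked as genes that neither RNA should hold, so they cannot decide on a rise of genes that only the reference lacks. Of them 26 were higher in liver and 7 lower, down to -2.68, so the reference held some. A general rise of genes that the reference lacks stays open. Pancreas RNA stays open: of the same 14 acinar genes, 78.6% were at least 2-fold higher, but the abundant transcripts Cel (0.22) and Amy2a5 (0.53), each on 1 probe, were not. Acinar genes expressed by liver itself were not counted, and no biological explanation was tested.

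Array 1 stood apart from arrays 2 and 3: 244 probes lay at least 1 log2 unit from the mean of the other arrays, 214 of them (87.7%) lower on array 1. The SD of this deviation was 0.41, against 0.22 for arrays 2 and 3. A shift with probe number as the whole cause is argued against, since after subtraction of block medians the correlation of array 1 with the mean of the others was 0.937 (0.936 before), against 0.984 for arrays 2 and 3, and blocks held 4.82% of the variance of the deviation. A few outlying probes are argued against by the rank correlation, at most 0.890 for array 1 and 0.962 for arrays 2 and 3. Differences in labelling or hybridisation stay open and untested.

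Turning the sign of 1 array at a time gives, with the real signs, 4 patterns, too few for a share under 0.05. With the real signs 3535 genes passed the limma test and 3731 had an unadjusted p under 0.05, and 1 of the 4 patterns, the real one, gave as many genes. The highest count of the others was 0, with at most 7 genes at an unadjusted p under 0.05. Because the arrays repeat 1 RNA pair, a turned array cancels every ratio that repeats. Low counts were thus fixed in advance and lend no weight to the 3535.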
